A study of Rattus norvegicus with 68 samples.

How the data were processed

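The blood transcripts of 34 male F344/N rats given a single oral gavage of acetaminophen in ethyl cellulose were measured on dual-colour oligonucleotide arrays. The rats fell into 9 groups by dose (150, 1500 or 2500 mg/kg) and time (6, 12 or 24 h), with 4 rats in each, or 3 in the 150 and the 1500 mg/kg groups at 12 h. Each rat was hybridised on 2 arrays of opposite dye orientation against a vehicle-treated control of its time, and the dyes were taken from the labels. By the design description the control of 6 h and of 12 h was a pool of 4 animals and that of 24 h a pool of 6. The labels of the 6 and 12 h arrays carry a single rat number for the control where those of 24 h name a pool, so that a single control animal at 6 and 12 h cannot be ruled out from the labels. The widened standard errors took pools of 4 and 6 animals, and a single animal would widen them further.

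The values were log10 ratios of both dyes for 22075 probes, deposited by the authors, and how they were background-corrected and normalized is not given in the sources used here. They were limited to between -2 and 2, had array medians between -0.00352 and 0, and looked like ratios that a scanner's feature extraction had already normalized within each array. The direction of the ratio is not stated with the values. It was taken as Cy5 over Cy3, as is usual for such log10 ratios, likely but not certain. Exact zeros made up 2.76% of the array values (41379) and values at the limit 0.493% (7406, of which 98 lay on probes with a single gene). Neither kind was left out. Control spots were not marked, and 362 unnamed probes with a mean dye log10 ratio under -1 are likely to be such spots. They stayed in the probe counts, while no gene value uses them. The 2 arrays of a rat correlated before turning by -0.30 to 0.86 (rat 4137) over probes, positively in 28 of 34 rats, and 10.8% of the named probes had a mean dye ratio over 1.5-fold. The lowest correlation of an array with the mean of the others was -0.24, for 1 array of rat 3631, and the next was 0.36.

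Log10 ratios were converted to log2 (times 3.32), turned to treated over control, and averaged over the 2 arrays of a rat, which counted as 1 replicate. Dye effects that are the same on both arrays cancel in this mean. Of the probes, 12750 were listed with 1 gene, 5 with several and 9320 with none, and 12720 of the first were named by matching their Entrez identifiers to current rat gene symbols of the GRCr8 assembly, which was used for names alone. Values of a gene are means over its probes, and 2266 of 9653 genes had over 1 probe.

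Tests used limma 3.58.1 in R 4.3.3 with the data.table package, version 1.17.8. A model with a mean for each of the 9 groups was fitted to all 34 rats (lmFit and eBayes, 25 residual degrees of freedom, prior degrees of freedom 1.55 for probes and 1.73 for genes). The 21 comparisons were each group against 0, which is the vehicle control, the 3 pairs of doses within each time, and the change of the difference between 2500 and 150 mg/kg between each pair of times. The control of a time was 1 sample, and a test against it leaves out the control's own spread. Probes passed at a Benjamini-Hochberg adjusted p under 0.05 over all probes. Adjusted p of named genes come from the same model fitted to the 9653 gene values.

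Before the data were examined, 22 gene lists were fixed: neutrophil, monocyte and macrophage, B cell, T cell, NK and cytotoxic, MHC class II, erythroid, platelet, interferon response, inflammatory signalling, Nrf2 and oxidative stress, p53 targets, ER stress and integrated stress response, heat shock, glucocorticoid response, glycolysis and hypoxia, oxidative phosphorylation, cytosolic ribosomal proteins, proteasome, cell cycle, clock, and liver-enriched transcripts. They were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation. A list needed 5 measured genes, and members were matched by symbol, older symbols included. After the values were available, 2 older symbols that point to a different gene were left out on the names alone.

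The design, the alternatives and the rule for named genes were also fixed then. The rule took genes with the same sign in every rat of the group. For 2500 mg/kg it took the 10 highest and 10 lowest means among genes that passed against the control and against 150 mg/kg, for 1500 mg/kg the 5 highest and 5 lowest, and for 150 mg/kg the 3 highest and 3 lowest that passed against the control. Where fewer than 5 genes passed in a direction, the condition against 150 mg/kg was dropped for that direction. It also took up to 4 members with the smallest adjusted p of each list described, and the 3 highest and 3 lowest of each change over time. Other genes are said to have been chosen after their values were seen, and members of lists that ran against their list, and Serpinb1a at 24 h after 150 mg/kg, were chosen in that way too.

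The alternatives fixed beforehand were the median of each array set to 0, arrays scaled to the same spread, arrays kept apart with a dye term and the rat as a random block, the rats of the compared times alone, robust moderation, the 20% of probes with the poorest agreement between dye orientations left out, standard errors widened for the animals pooled in the control, an estimated correlation for the lists, genes in place of probes, the opposite sign, and each rat left out in turn. The scaling used limma's normalizeMedianAbsValues in place of the planned scale method, which gave undefined values on this matrix. Leaving out the probes with poor agreement stood in for a filter on signal or missing values, as planned for files without them. With arrays kept apart, the estimated correlation between the arrays of a rat was -0.0345. Added after seeing the data were the removal of the mean dye profile from each array, with slopes over all probes and then over named probes, the omission of rats 3631 and 4137 together, the gene lists with scaled arrays, and the comparison of doses with held-out 150 mg/kg rats at 12 h without rat 4137.

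The model was tested on simulated data of the same size. With 22075 probes and shifts of log2 0.5, 1 and 1.5, it recovered 59.7%, 79.1% and 98.5% of the shifted probes for 2500 mg/kg at 24 h (14 false calls), and 68.7%, 86.6% and 98.5% for 1500 mg/kg at 12 h (10 false calls). For 2500 against 150 mg/kg at 24 h it recovered 47.8%, 76.1% and 89.4% (4 false calls), and for the change from 6 to 24 h 29.9%, 58.2% and 90.9% (4 false calls). Of 22 lists in 9653 genes, only a T cell list shifted by -0.5 was called. Real calls may hold more false ones, as 18 of 131 lists passed with an estimated correlation.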

Results

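Acetaminophen (APAP) is an analgesic that injures the liver at high doses. Its effect on the transcripts of blood was measured in male rats of the inbred strain F344/N, killed 6, 12 or 24 h after oral doses of 150, 1500 or 2500 mg/kg. Each of 34 rats was compared with vehicle-treated control RNA of the same time on 2 arrays that differed in which sample carried which dye, 68 arrays in all. There were 4 rats per dose and time, or 3 at 150 and at 1500 mg/kg at 12 h, which limits the precision of every value. The arrays held 22075 probes, and 12750 of them carried a single gene name. A value is the log2 ratio of a treated rat to the control, averaged over the 2 arrays of the rat, and an error is the SD over the rats of a group unless stated otherwise. The direction of the ratio is likely but not stated, and with the opposite one every sign given here would turn. The control of each time was 1 RNA sample, described as a pool, although the labels of the 6 and 12 h arrays carry a single rat number for it. Its own spread is outside the tests against it, while the comparisons between doses of a time rest on single rats and are free of this limit.

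At 24 h after 2500 mg/kg, transcripts of neutrophil proteins were among the named transcripts that rose above the vehicle control. Serpinb1a, which codes for an inhibitor of neutrophil proteases, rose by log2 3.37 ± 0.88 (SD, n = 4 rats), or 10.3-fold (limma adjusted p = 1.47e-07). S100a9 and S100a8, the subunits of the antimicrobial protein calprotectin, rose by 3.08 ± 1.40 and 2.90 ± 0.89. Il1r2, a decoy receptor for interleukin-1, rose by 1.97 ± 0.49, and Mmp8, the collagenase of neutrophil granules, by 1.58 ± 0.84. Anxa1, a phospholipid-binding protein induced by glucocorticoids, rose by 2.05 ± 0.77, and Ccl2, which attracts monocytes, by 1.86 ± 0.71, although 1 of its 8 array values was exactly 0. Tf and Rbp4, which code for the plasma carriers of iron and retinol, rose by 2.33 ± 0.70 and 1.51 ± 0.53. Zdhhc2, a palmitoyltransferase, was higher by 1.52 ± 0.73 (adjusted p = 0.00343), with 1 of its 8 array values at exactly 0.

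Other named transcripts fell at 24 h after 2500 mg/kg. Bpgm, which makes the red cell regulator of oxygen release from haemoglobin, fell to -1.62 ± 0.31 (SD, n = 4 rats; limma adjusted p = 4.89e-09). Gpx1, a glutathione peroxidase, fell to -1.83 ± 0.62, Cmas, which activates sialic acid, to -1.83 ± 0.50, and Kpna1, an importin, to -1.70 ± 0.35. Myl9, a myosin light chain, fell to -1.69 ± 0.53, and Rab27b, a small GTPase of granule secretion, to -1.71 ± 1.18. The secreted phospholipases Pla2g2a and Pla1a stood at -1.78 ± 0.44 and -1.63 ± 0.37, and Clec4a3, a lectin receptor of myeloid cells, at -1.71 ± 0.32. Abi3, an adaptor of the actin cytoskeleton, had the lowest mean, -2.30 ± 1.85, with the widest spread (adjusted p = 0.000683). For Abi3 and Rab27b, 1 of 8 array values lay at the scale limit. Chosen to differ from 150 mg/kg too, these 20 genes had adjusted p from 5.72e-06 (Serpinb1a) to 0.0324 (Abi3) against it.

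The 1500 mg/kg group at 24 h had many of the same leading genes. Serpinb1a rose by log2 3.45 ± 0.70 (SD, n = 4 rats; 10.9-fold; limma adjusted p = 1.26e-07), S100a9 by 3.38 ± 0.85, S100a8 by 2.85 ± 1.03, Tf by 2.45 ± 0.91 and Il1r2 by 2.04 ± 0.78. Cmas fell to -2.07 ± 0.27, Kpna1 to -1.94 ± 0.29 and Gpx1 to -1.82 ± 0.31. Ranbp10, which binds the GTPase Ran, fell to -1.80 ± 0.22, and Eef1e1, an auxiliary component of the complex of tRNA synthetases, to -1.51 ± 0.19. Against 150 mg/kg, again by choice, these 10 had adjusted p from 1.45e-06 (Kpna1) to 0.00026 (Ranbp10).

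**Figure D1:**
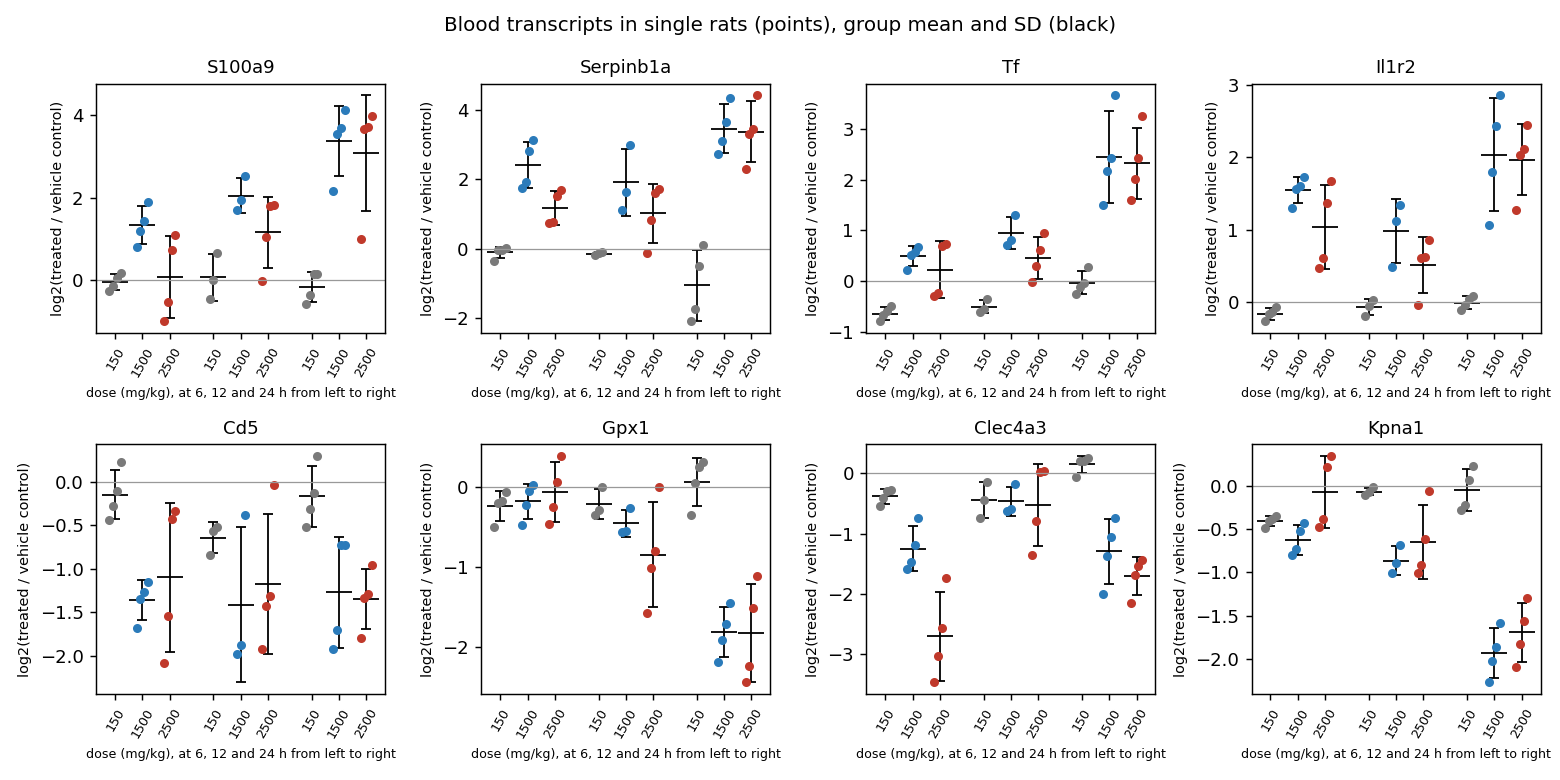
Log2 ratios of treated rats to the vehicle control (vertical axes) for 8 transcripts, by dose and by time (horizontal axes), with a point per rat and the group mean and SD in black. At 24 h the 1500 and 2500 mg/kg rats lie apart from the 150 mg/kg rats for Serpinb1a (means 3.45, 3.37 and -1.06) and for Kpna1 (means -1.94, -1.70 and -0.049).

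Gene lists fixed beforehand gave the groups behind these genes. Of 18 neutrophil genes, 9 rose and 0 fell at 24 h after 1500 mg/kg (13 and 0 adjusted over the list alone), with a list median of 0.37 (camera adjusted p = 2.27e-16, or 0.00043 with an estimated correlation). After 2500 mg/kg, 10 rose and 1 fell (10 and 1 over the list alone), with a median of 0.21 (adjusted p = 6.65e-07, or 0.0616 with estimated correlation). Besides those above, Alox5, the enzyme that starts leukotriene synthesis, rose by 1.26 ± 0.63 and 1.28 ± 0.41. The member that fell was Fcnb, a ficolin, at -0.45 ± 0.14 (SE) after 2500 mg/kg, while it rose by 0.45 ± 0.14 (SE) after 1500 mg/kg. Of 19 T cell genes, 10 fell after 1500 mg/kg and 11 after 2500 mg/kg, and 0 rose (13 and 13 fell over the list alone). The T cell list medians were -0.34 and -0.19 (adjusted p = 4.29e-07 and 0.000264, or 0.0162 and 0.101 with estimated correlation). These are over gene means. Within rats they ran from -0.51 to -0.11 and from -0.34 to -0.29. Cd6, a receptor of T cells, fell to -1.02 ± 0.46 and -1.07 ± 0.33, Lck, the kinase that starts T cell receptor signalling, to -0.90 ± 0.65 and -0.96 ± 0.36. Cd5, a brake on that signalling, fell to -1.27 ± 0.64 and -1.35 ± 0.34. Ptprcap, a partner of the phosphatase CD45, fell to -0.74 ± 0.47 after 1500 mg/kg. Without rat 3623 the adjusted p of Cd5 and of Ptprcap at this dose was 0.0539 and 0.0678. Of the 54 named genes called at this dose, 13 lost their call without rat 3623, 10 without rat 3624 and 5 without rat 3626 (adjusted p up to 0.374, 0.336 and 0.201). Without any one of 12 other rats 1 did (adjusted p up to 0.0533). With only the rats of 24 h, 15 of the 54 lost their call (adjusted p up to 0.223), with scaled arrays 5 (up to 0.155) and with standard errors widened for the control 12 (up to 0.252). Of 57 named genes called after 2500 mg/kg, 6 lost their call with only the rats of 24 h (up to 0.168) and 3 with widened standard errors (up to 0.0774), and 1 lost its call without rat 3630, Blnk (adjusted p = 0.0766), and 2 without rat 3631, Calr and Cd37 (0.164 and 0.0934). Of 11 B cell genes, 5 fell at each of these doses (5 and 6 over the list alone). Spib, a transcription factor of B cells, fell to -0.86 ± 0.24 and -0.69 ± 0.63. The B cell list had adjusted p = 0.000133 and 0.0112 (or 0.00254 and 0.0643 with estimated correlation).

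Of 25 erythroid genes, 9 fell and 0 rose at 24 h after 1500 mg/kg (11 and 0 over the list alone; median -0.11, camera adjusted p = 9.52e-07, or 0.0113 with estimated correlation). After 2500 mg/kg, 10 fell and 2 rose (13 and 3 over the list alone; median -0.15, adjusted p = 0.00117, or 0.101 with estimated correlation). Bnip3l, which clears mitochondria from maturing red cells, fell to -1.14 ± 0.29 after 1500 mg/kg, and Nfe2, a transcription factor of red cells and platelets, to -1.09 ± 0.51 after 2500 mg/kg. The blood group gene Rhd fell to -0.97 ± 0.36 and -1.07 ± 0.41, and Epb42, a protein of the red cell membrane skeleton, to -0.62 ± 0.22 and -0.86 ± 0.45. The pair that rose after 2500 mg/kg was Alas2, which starts haem synthesis, at 0.60 ± 0.22 (SE) and Ank1, the red cell ankyrin, at 0.61 ± 0.17 (SE). Of 15 platelet genes, 6 fell after 2500 mg/kg (6 over the list alone). Gp1bb, a subunit of the receptor for von Willebrand factor, had -1.02 ± 0.25, the chemokine Pf4 -0.84 ± 0.43, Clu -0.62 ± 0.24 and the ADP receptor P2ry12 -0.53 ± 0.44. The platelet list had a median of -0.10 (adjusted p = 0.046, or 0.413 with estimated correlation). Without rat 3631 the median was 0.029 (adjusted p = 0.524). The call also ended with scaled arrays (adjusted p = 0.111) and after the mean dye profile was removed from each array, with slopes over all or over named probes (0.0585 and 0.0766). Without any one of 10 rats of other groups its adjusted p lay between 0.0501 and 0.0541. After 1500 mg/kg the platelet list was not called (1 rose, 0 fell, adjusted p = 0.971, with a median of -0.012 and a mean of -0.019 beside a test that leant upwards).

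Lists of the translation, energy and protein breakdown machinery were called downwards at 24 h after 2500 mg/kg. Of 50 cytosolic ribosomal protein genes, 28 fell and 0 rose (30 and 0 over the list alone, median -0.50, adjusted p = 9.45e-09, or 0.413 with estimated correlation). Rpl19 fell to -1.07 ± 0.29, Rpl29 to -0.87 ± 0.37 and Rpsa to -0.80 ± 0.064. Of 53 genes of oxidative phosphorylation, 26 fell and 1 rose (28 and 1 over the list alone, median -0.23, adjusted p = 4.52e-05, or 0.413 with estimated correlation). The member that rose, Ndufa7 of complex I, had 0.15 ± 0.066. Of 33 proteasome genes, 18 fell and 1 rose (20 and 1 over the list alone, median -0.25, adjusted p = 4.52e-05, or 0.413 with estimated correlation). The one that rose, the immunoproteasome subunit Psmb10, had 0.53 ± 0.21. Of the ribosomal protein genes after 1500 mg/kg, 14 fell and 0 rose (25 and 0 over the list alone, median -0.37, adjusted p = 1.82e-09, or 0.282 with estimated correlation). In oxidative phosphorylation after this dose, 6 fell and 0 rose (13 and 0 over the list alone, median -0.15, adjusted p = 5.71e-05, or 0.369 with estimated correlation). In the proteasome list 5 fell and 0 rose (11 and 2 over the list alone, median -0.14, adjusted p = 3.25e-05, or 0.269 with estimated correlation). Without rat 3624 the oxidative phosphorylation list had adjusted p = 0.0505 after 1500 mg/kg. The arrays differed in dye strength, the slope of an array's dye ratios on their mean over all arrays. Its means were 1.28, 1.14 and 0.72 in the 150, 1500 and 2500 mg/kg rats at 24 h, beside ribosomal list medians of -0.00024, -0.37 and -0.50. Dye effects equal on both arrays cancel in a rat's mean. With the dye profile removed over named probes the last 2 medians were -0.38 and -0.52, and the calls of all 3 lists stood. These lists differed between the sides of the high-dose split with most probe calls. So did the slope difference of paired arrays, which does not cancel. In rats 3625, 3626, 3628 and 3629 ribosomal, oxidative phosphorylation and proteasome medians ran from -0.34 to 0.011, -0.13 to 0.035 and -0.16 to 0.060. In rats 3623, 3624, 3630 and 3631 they ran from -0.78 to -0.56, -0.51 to -0.14 and -0.36 to -0.19. Of 24 genes of the ER stress and integrated stress response, 6 fell and 0 rose (6 and 0 over the list alone, median -0.12, adjusted p = 0.0428, or 0.413 with estimated correlation) after 2500 mg/kg. Asns, which makes asparagine, stood at -0.63 ± 0.15. Without rats 3628, 3629 or 3630, the ER stress list had adjusted p = 0.0707, 0.124 and 0.142.

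The lists of inflammatory signalling and of transcripts enriched in liver were called upwards at 24 h. Of 33 inflammatory signalling genes, 6 rose and 2 fell (8 and 2 over the list alone, median 0.071, adjusted p = 0.000827, or 0.00291 with estimated correlation) after 1500 mg/kg. After 2500 mg/kg 8 rose and 1 fell (9 and 1 over the list alone, median 0.043, adjusted p = 0.0337, or 0.0666 with estimated correlation). Sod2, the superoxide dismutase of mitochondria, rose by 1.24 ± 0.55 and 1.11 ± 0.49, and the chemokine Cxcl2 by 0.67 ± 0.62 after 2500 mg/kg. Without rat 3628 the inflammatory list had adjusted p = 0.116 after 2500 mg/kg. Of 42 genes with transcripts enriched in liver, 5 rose and 0 fell (6 and 0 over the list alone, median 0.049, adjusted p = 0.000163, or 0.0435 with estimated correlation) after 1500 mg/kg. After the higher dose 15 rose and 1 fell (15 and 3 over the list alone, median 0.067, adjusted p = 0.000727, or 0.101 with estimated correlation). Ttr, which carries thyroid hormone and Rbp4, rose by 0.32 ± 0.19 and 0.55 ± 0.37, and Apoc1 by 0.15 ± 0.079 and 0.25 ± 0.14. Apoa1 fell to -0.20 ± 0.071 (SE) after 2500 mg/kg. Without rat 3623, Ttr and Apoc1 had adjusted p = 0.194 and 0.251 after 1500 mg/kg. Without rat 3624, Ttr had 0.0534. Further lists passed after 1500 mg/kg. Of 19 monocyte and macrophage genes, 4 rose and 1 fell (4 and 1 over the list alone, median 0.053, adjusted p = 0.006, or 0.0435 with estimated correlation). The receptor Tlr2 had 1.71 ± 0.86 and Clec4a3 -1.29 ± 0.54. Of 32 interferon response genes, 9 rose and 1 fell (12 and 3 over the list alone, median 0.047, adjusted p = 0.000823, or 0.153 with estimated correlation). The antiviral synthetase Oas1a had 1.08 ± 0.59 and Ifi27 -0.21 ± 0.055 (SE). Of 23 glucocorticoid response genes, 6 rose and 1 fell (6 and 1 over the list alone, median 0.015, adjusted p = 0.0253, or 0.369 with estimated correlation), with Anxa1 at 1.84 ± 0.24 (SE). Without rat 3625 the monocyte, interferon and glucocorticoid lists had adjusted p = 0.0618, 0.132 and 0.151. The last had 0.157 without rat 3626 and 0.0556 without rat 3631.

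The remaining lists were not called at 24 h after 2500 mg/kg. Of 36 Nrf2 and oxidative stress genes, 9 fell and 6 rose (camera adjusted p = 0.204), and of 22 heat shock genes, 7 fell and 1 rose (adjusted p = 0.308). The interferon list held 5 genes that rose and 7 that fell (adjusted p = 0.946, with a median of -0.0076 and a mean of 0.00075). Of 22 p53 targets, 3 rose and 3 fell (adjusted p = 0.946, median -0.022, mean 0.014). The glucocorticoid list had adjusted p = 0.372 (median -0.038, mean 0.15), the monocyte and macrophage list 0.325, the 20 NK and cytotoxic genes 0.186, and the 6 MHC class II genes 0.325. The 28 genes of glycolysis and hypoxia had adjusted p = 0.878, the 34 cell cycle genes 0.574 and the 11 clock genes 0.443.

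Against the control, 4988 of 22075 probes passed at 24 h after 2500 mg/kg, 2282 higher and 2706 lower. After 1500 mg/kg 1140 passed, 330 higher and 810 lower (limma, Benjamini-Hochberg adjusted p under 0.05). At 150 mg/kg 0 passed with limma, with 692 probes at an unadjusted p under 0.05. Without rat 3617 or rat 3620 the count was 1. Fitting the rats of 24 h alone gave 993 probes for 2500 mg/kg and 358 for 1500 mg/kg. Allowing for the spread of a control pool of 6 animals gave 1611 and 405. For 1500 mg/kg the count was 582 without rat 3623, 1802 without rat 3625 and 1809 without rat 3631, a rat of the 2500 mg/kg group with the widest spread of log2 ratios over genes (SD 0.60).

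**Figure D2:**
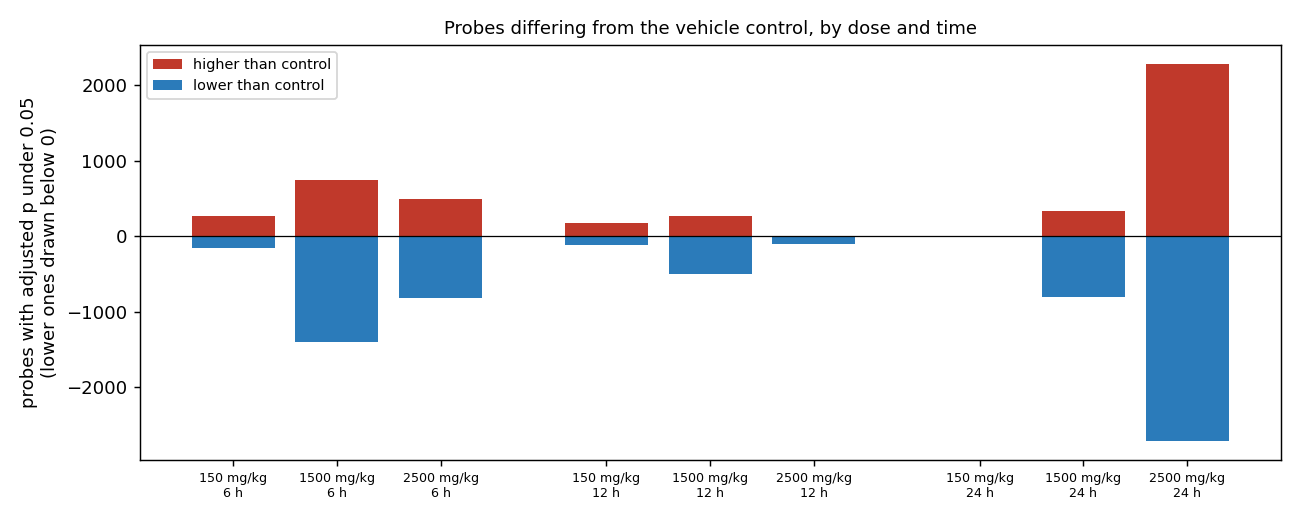
Number of probes (vertical axis) higher (upward bars) or lower (downward bars) than the vehicle control at an adjusted p under 0.05, for each dose and time (horizontal axis). The counts run from 0 at 24 h after 150 mg/kg to 4988 at 24 h after 2500 mg/kg.

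Comparing doses asked whether the response grew with the dose, with the control sample cancelling out. At 24 h the neutrophil list was called upwards for both high doses against 150 mg/kg. Of 18, 8 were higher and 0 were lower (10 and 0 over the list alone, median 0.35, adjusted p = 9.32e-18, or 0.000243 with estimated correlation) after 1500 mg/kg. After 2500 mg/kg 8 were higher and 0 were lower (10 and 1 over the list alone, median 0.26, adjusted p = 1.98e-08, or 0.0246 with estimated correlation). The erythroid list was called downwards. Of 25, 6 were lower and 0 were higher (10 and 0 over the list alone, median -0.14, adjusted p = 1.54e-06, or 0.012 with estimated correlation) after 1500 mg/kg. For 2500 mg/kg 7 were lower and 0 were higher (9 and 1 over the list alone, median -0.12, adjusted p = 0.000673, or 0.0929 with estimated correlation). The B cell list was lower (adjusted p = 0.00137 and 0.0325, or 0.00958 and 0.0855 with estimated correlation). So was the T cell list (adjusted p = 3.65e-05 and 0.00127, or 0.0492 and 0.172 with estimated correlation). The B cell call at 2500 mg/kg ended without rats 3619, 3620, 3629 or 3630 (adjusted p = 0.0548, 0.0599, 0.1 and 0.0806), and with scaled arrays (0.0554). Of the liver list, 3 were higher and 0 were lower (4 and 0 over the list alone, median 0.065, adjusted p = 0.000108, or 0.0424 with estimated correlation) after 1500 mg/kg. For that list after 2500 mg/kg, 7 were higher and 0 were lower (9 and 0 over the list alone, median 0.089, adjusted p = 0.000268, or 0.0847 with estimated correlation). Other lists were also called. Those of inflammatory signalling were called upwards (adjusted p = 0.00235 and 0.0341, or 0.00958 and 0.0847 with estimated correlation). Those of ribosomal proteins, oxidative phosphorylation and the proteasome were called downwards after both doses, with adjusted p of at least 0.329 with estimated correlation. After 1500 mg/kg the monocyte, interferon and glucocorticoid lists were called upwards and the NK list downwards, and after 2500 mg/kg the platelet list downwards (lowest adjusted p 0.115 with estimated correlation). The calls of the monocyte, NK, interferon, glucocorticoid and proteasome lists after 1500 mg/kg and of the platelet and inflammatory lists after 2500 mg/kg each ended without some single rat (adjusted p up to 0.142 and 0.383). With scaled arrays the monocyte and glucocorticoid calls ended (0.0766 and 0.0542), and with the dye profile removed over all probes that of the NK list (0.0502). In all, 1152 probes differed between 2500 and 150 mg/kg (445 higher and 707 lower), and 281 between 1500 and 150 mg/kg (80 higher and 201 lower). Without rats 3617, 3618 and 3629 the first count was 633, 636 and 1752. The second was 166 without rat 3618. With the rats of 24 h alone they were 112 and 46.

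Between 2500 and 1500 mg/kg at 24 h, 0 probes passed with limma, with 1635 at an unadjusted p under 0.05. Of 22 lists only the platelet and interferon lists were called. Of 15 platelet genes, 0 were lower and 0 were higher (4 and 0 over the list alone, median -0.10, adjusted p = 0.00108, or 0.474 with estimated correlation). Of 32 interferon response genes, 0 were lower and 0 were higher (1 and 0 over the list alone, median -0.13, adjusted p = 0.000684, or 0.474 with estimated correlation). Without rat 3631 the platelet list had adjusted p = 0.429 with a median of 0.030, and without rat 3625 the interferon list had adjusted p = 0.3. Without single rats the probe count was at most 12.

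**Figure D3:**
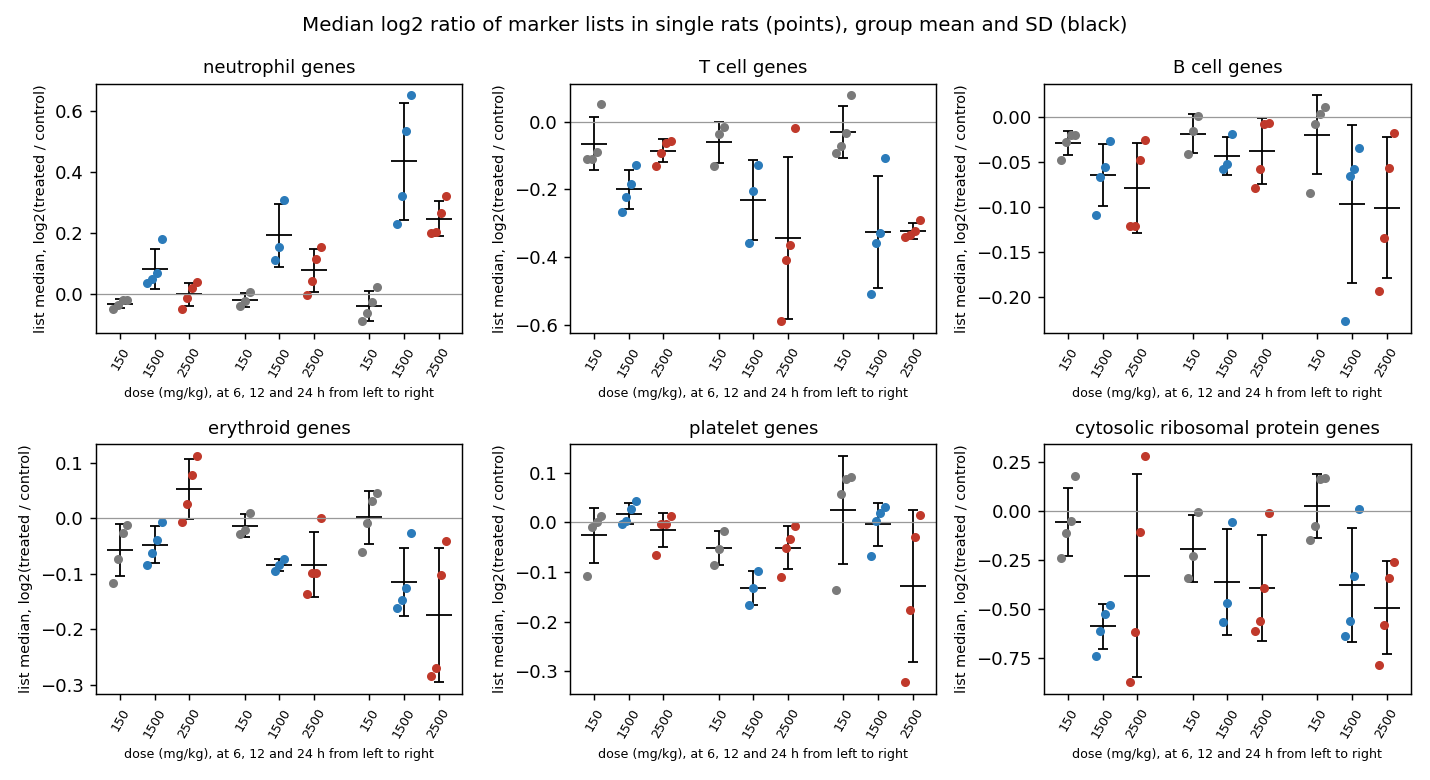
Median log2 ratio to the vehicle control of the members of 6 gene lists (vertical axes) in each rat, by dose and by time (horizontal axes). At 24 h the group medians of the neutrophil list were -0.029, 0.37 and 0.21 after 150, 1500 and 2500 mg/kg, and those of the cytosolic ribosomal protein list -0.00024, -0.37 and -0.50.

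At 6 h, the earliest time, 10 named transcripts that fell after 2500 mg/kg passed both against the control and against 150 mg/kg. Clec4a3 fell to log2 -2.70 ± 0.74 against the control (SD, n = 4 rats; limma adjusted p = 1.15e-08) and also differed from 150 mg/kg (adjusted p = 0.000398). Spib fell to -1.43 ± 0.23, Dusp6, a phosphatase that switches off ERK, to -1.67 ± 0.30, and Dusp22, a further phosphatase, to -1.36 ± 0.31. Ramp1, a partner of the receptor for the peptide CGRP, fell to -1.63 ± 0.50, and the diacylglycerol kinase Dgkg to -1.35 ± 0.47. Myof, which acts in membrane repair, fell to -1.34 ± 0.17, and the LIM protein Crip1 to -1.25 ± 0.20. Vamp4, a protein of vesicle fusion, stood at -1.10 ± 0.22, and Mcm5, part of the replication helicase, at -0.83 ± 0.50 (adjusted p = 0.0433 against 150 mg/kg). Between 2500 and 150 mg/kg 18 probes passed (1 higher and 17 lower). Between 1500 and 150 mg/kg 3 passed (1 higher and 2 lower). Averaged by gene, 4 genes differed between 1500 and 150 mg/kg, named here after their values were seen. Il1r2 was higher by 1.71 ± 0.29 (SE) and Dgat2, which makes triglycerides, by 0.77 ± 0.15 (SE). Crip1 stood at -1.05 ± 0.18 (SE) and the elongation factor Eef2 at -0.64 ± 0.092 (SE). Without rats 3588, 3598, 3597 and 3587 the count for 2500 against 150 mg/kg was 3, 7, 8 and 9. The 3 probes for 1500 mg/kg became 1 to 14 without single rats. With every array scaled to the same spread, these counts were 120 and 347.

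At 6 h after 2500 mg/kg, transcripts that rose were named from the test against the control alone. Sat1, which breaks down polyamines, rose by log2 1.28 ± 0.97 (SD, n = 4 rats; limma adjusted p = 0.00358), the interferon-induced Ifit3 by 1.21 ± 0.91, Serpinb1a by 1.18 ± 0.49 and Il1r2 by 1.03 ± 0.58. Prelid3b, a lipid carrier of mitochondria, rose by 1.03 ± 0.40, H2ax, a histone that marks broken DNA, by 0.97 ± 0.71. The GABA receptor subunit Gabra4 rose by 0.85 ± 0.095, and Gadd45a, a growth arrest gene, by 0.82 ± 0.78. Gipc2 and Myo5a, a motor protein, had means of 0.86 ± 1.16 and 0.83 ± 1.25 that rested on rat 3595. Without it they were 0.29 and 0.20 (adjusted p = 0.479 and 0.698). Of the 35 genes called at this dose, 7, 6, 11 and 12 lost their call without rats 3595, 3596, 3597 and 3598. Their adjusted p were up to 0.698, 0.192, 0.432 and 0.258. Each of 28 rats of other groups ended between 1 and 3 calls (adjusted p up to 0.0585). With widened standard errors 22 lost their call (up to 0.436), and with only the rats of 6 h 3 did (up to 0.127). At 6 h after 1500 mg/kg, Serpinb1a rose by 2.40 ± 0.67 (5.29-fold), Il1r2 by 1.55 ± 0.18, S100a8 by 1.53 ± 0.48, S100a9 by 1.33 ± 0.46 and the complement protease Cfd by 1.05 ± 0.21. Without rats 3592 or 3593 both S100a9 and Cfd missed the threshold, as did S100a9 without rat 3594. Of the 35 genes called at this dose, 1, 3, 3 and 2 lost their call without rats 3591, 3592, 3593 and 3594 (adjusted p up to 0.0811, 0.0810, 0.124 and 0.0545), and 11 with widened standard errors (up to 0.238). Irf2bpl, which binds interferon regulatory factor 2, fell to -1.76 ± 0.27, the RNA-binding Hnrnpa2b1 to -1.68 ± 0.39, and Ramp1 to -1.65 ± 0.20. Dennd2d, which acts on Rab GTPases, fell to -1.63 ± 0.20, and Psmg4, a chaperone of proteasome assembly, to -1.62 ± 0.13. Genes named here were not chosen against 150 mg/kg, where Irf2bpl also fell.

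Most lists called against the control at 6 h were called downwards. Of 50 ribosomal protein genes after 1500 mg/kg, 29 fell and 0 rose (36 and 0 over the list alone, median -0.58, adjusted p = 4.45e-18, or 0.359 with estimated correlation). Rpl8 had -1.46 ± 0.18. Of 53 oxidative phosphorylation genes, 22 fell and 1 rose (32 and 1 over the list alone, median -0.20, adjusted p = 1.36e-09, or 0.359 with estimated correlation). Sdhb had -1.15 ± 0.22. Of 33 proteasome genes, 9 fell and 0 rose (12 and 0 over the list alone, median -0.14, adjusted p = 6.71e-05, or 0.406 with estimated correlation). Of the T cell genes, 8 fell and 0 rose (8 and 0 over the list alone, median -0.15, adjusted p = 7.44e-05, or 0.182 with estimated correlation). Lat, an adaptor of the T cell receptor, fell to -1.34 ± 0.15. Of the B cell genes, 4 fell and 0 rose (5 and 0 over the list alone, median -0.050, adjusted p = 0.0102, or 0.0828 with estimated correlation). Spib fell to -1.24 ± 0.17. Ms4a1, the B cell antigen CD20, fell to -0.52 ± 0.070, although its 2 probes had opposite signs. Of the Nrf2 and oxidative stress genes, 7 fell and 0 rose (9 and 0 over the list alone, median -0.079, adjusted p = 0.0404, or 0.406 with estimated correlation). Sod1 fell to -0.68 ± 0.11. Of the neutrophil genes, 4 rose and 1 fell (4 and 1 over the list alone, median 0.10, adjusted p = 0.0457, or 0.406 with estimated correlation). Fcnb fell to -1.02 ± 0.19. The neutrophil call ended without any one of 8 rats (adjusted p from 0.0502 to 0.128). That of the Nrf2 list ended without rats 3591, 3593 or 3631 (0.0579, 0.0535 and 0.0606). Both calls also ended with scaled arrays (0.15 and 0.0753) and with the dye profile removed over named probes (0.0632 and 0.0611). Of 11 B cell genes after 2500 mg/kg, 5 fell and 0 rose (5 and 0 over the list alone, median -0.037, adjusted p = 0.00123, or 0.0124 with estimated correlation). In the T cell list 5 fell and 0 rose (7 and 0 over the list alone, adjusted p = 0.00676, or 0.645 with estimated correlation). Its median was -0.17, and -0.13 to -0.058 within rats. In the oxidative phosphorylation list 8 fell and 1 rose (12 and 1 over the list alone, median -0.13, adjusted p = 6.4e-05, or 0.684 with estimated correlation). Among ribosomal protein genes 5 fell and 0 rose (15 and 1 over the list alone, median -0.29, adjusted p = 7.95e-06, or 0.684 with estimated correlation). The ribosomal medians of rats 3597 and 3598 were -0.87 and -0.62, while that of rat 3595 was -0.11 and that of rat 3596 was 0.28, so that the median over the group describes neither pair. Without rat 3597 the T cell, oxidative phosphorylation and ribosomal lists had adjusted p = 0.1, 0.1 and 0.199. The dye strength means of the 150, 1500 and 2500 mg/kg rats at 6 h were 1.27, 0.62 and 0.67, beside ribosomal list medians of -0.051, -0.58 and -0.29. With the dye profile removed over named probes the last 2 medians were -0.58 and -0.28, and the calls stood. Between 2500 and 1500 mg/kg 0 probes passed with limma (491 at an unadjusted p under 0.05, and 2 without rat 3595, 1 without rat 3624 and 1 without rat 3626). Of the 22 lists 11 were called, with 0 genes passing in any of them. Called upwards were the lists of ribosomal proteins (median 0.30, adjusted p = 9.48e-15), oxidative phosphorylation (median 0.092, adjusted p = 0.000169) and the proteasome (median 0.10, adjusted p = 0.000449). So were those of erythroid (median 0.088, adjusted p = 0.000883), T cell (median 0.14, adjusted p = 0.0164) and heat shock genes (median 0.050, adjusted p = 0.0178), and those of Nrf2 and oxidative stress (median 0.063, adjusted p = 0.0164) and ER stress (median 0.090, adjusted p = 0.0178). With an estimated correlation the lowest adjusted p of these 8 was 0.129. Called downwards were the neutrophil list (median -0.063, adjusted p = 0.000169, or 0.109 with estimated correlation), the inflammatory list (median -0.025, adjusted p = 0.0186, or 0.0683 with estimated correlation) and the monocyte and macrophage list (median -0.049, adjusted p = 0.000556, or 0.0474 with estimated correlation). Without rat 3596 the calls of oxidative phosphorylation, T cell, inflammatory, Nrf2, ER stress, heat shock and proteasome lists ended (adjusted p = 0.83, 0.224, 0.0936, 0.331, 0.358, 0.0936 and 0.368). The inflammatory call also ended without rats 3597 and 3598 (0.0515 and 0.0595), and that of ER stress without rat 3595 (0.133). Against 150 mg/kg, 6 lists were called for 1500 mg/kg, the neutrophil list upwards and those of ribosomal proteins, oxidative phosphorylation, the proteasome, T cells and B cells downwards (lowest adjusted p 0.165 with estimated correlation). For 2500 mg/kg 5 were called, the erythroid list upwards and those of ribosomal proteins, oxidative phosphorylation, T cells and B cells downwards (lowest adjusted p 0.0748 with estimated correlation). The B cell median was 0.0010, against the direction of its test. These last 4 calls and the B cell call for 1500 mg/kg each ended without some single rat (adjusted p up to 0.764), and the last also with the dye profile removed over named probes (0.0613). Lyz2, a lysozyme of the monocyte list named after its values were seen, stood at -2.21 ± 0.27 (SE) after 2500 mg/kg and at -0.81 ± 0.27 (SE) after 1500 mg/kg.

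Against the control at 6 h, 2149 probes passed after 1500 mg/kg, 746 higher and 1403 lower. After 2500 mg/kg 1301 passed, 490 higher and 811 lower (limma). With every array scaled to the same spread the counts were 6246 and 4470. Allowing for the spread of the control, taken as a pool of 4 animals, gave 408 and 186. Without single rats the first ran from 1094 to 3470 and the second from 575 to 2366, both highest without rat 3631.

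At 12 h after 1500 mg/kg, with 3 rats, the neutrophil transcripts S100a9 and Serpinb1a rose by log2 2.05 ± 0.42 and 1.92 ± 0.97 (SD; limma adjusted p = 0.00729 and 0.00655). Cfd rose by 1.68 ± 0.56, Nudt4, a hydrolase of inositol pyrophosphates, by 1.43 ± 0.68, and Lyz2 by 1.24 ± 0.61. The platelet list was called downwards. Of 15 genes, 7 fell and 0 rose (7 and 0 over the list alone, median -0.15, adjusted p = 5.65e-05, or 0.231 with estimated correlation). Pf4 stood at -1.15 ± 0.58 and Gp1bb at -1.09 ± 0.44. Abi3 fell to -2.11 ± 0.39, Enpp1, which makes pyrophosphate, to -1.70 ± 1.08, the tetraspanin Tspan12 to -1.69 ± 0.94, and Cd2, a T cell adhesion protein, to -1.66 ± 0.50. Pex14, which imports proteins into peroxisomes, stood at -1.45 ± 0.23, with 2 of its 6 array values at exactly 0. Of the T cell genes, 6 fell and 0 rose (9 and 0 over the list alone, median -0.29, adjusted p = 0.000445, or 0.231 with estimated correlation). Of the erythroid genes, 4 fell and 0 rose (8 and 1 over the list alone, median -0.055, adjusted p = 0.00694, or 0.231 with estimated correlation). Tal1, a transcription factor of blood formation, fell to -0.82 ± 0.24. Of the neutrophil genes, 4 rose and 0 fell (5 and 1 over the list alone, median 0.19, adjusted p = 0.00534, or 0.231 with estimated correlation). With scaled arrays this call ended (adjusted p = 0.088). Of the glucocorticoid response genes, 3 rose and 1 fell (10 and 2 over the list alone, median 0.14, adjusted p = 0.000445, or 0.235 with estimated correlation). The transcription factor Cebpd rose by 1.06 ± 0.54. Among ribosomal protein genes, 7 fell and 0 rose (20 and 0 over the list alone, median -0.38, adjusted p = 6.07e-09, or 0.378 with estimated correlation). In oxidative phosphorylation, 4 fell and 1 rose (4 and 1 over the list alone, median -0.15, adjusted p = 5.68e-05, or 0.438 with estimated correlation). In the proteasome, 0 fell and 0 rose (2 and 0 over the list alone, median -0.094, adjusted p = 0.0169, or 0.58 with estimated correlation). Of the 35 genes called, 23, 18 and 18 lost their call without rats 4132, 4133 and 4134. Their adjusted p were up to 0.247, 0.306 and 0.240. Each of 7 rats of other groups ended 1 call (adjusted p up to 0.0514). With only the rats of 12 h 21 of the 35 lost their call (up to 0.101), with scaled arrays 13 (up to 0.132) and with widened standard errors 29 (up to 0.336). Without rat 4133 the erythroid and glucocorticoid lists had adjusted p = 0.0504 and 0.125. The proteasome list had 0.0811 without rat 4132 and 0.479 without rat 4134.

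The named genes at 12 h after 2500 mg/kg depended on the settings. All 33 genes called lost their call with scaled arrays (adjusted p from 0.0761 to 0.266), with only the rats of 12 h (0.150 to 0.199) and with widened standard errors (0.693 to 0.825). Cd2 fell to -1.82 ± 1.02 (SD, n = 4 rats; limma adjusted p = 0.0196), Cd5 to -1.17 ± 0.80, Ptpn22, a phosphatase that restrains T cell receptor signals, to -1.06 ± 0.71, and Jchain, which joins antibody units, to -1.04 ± 0.69. The nucleoporin Nup42, with 1 of 8 array values at exactly 0, fell to -1.36 ± 0.83, Ifi27l2b to -1.21 ± 0.82, and the ribosomal protein Rpl41 to -1.06 ± 0.86. The actin regulator Evl fell to -0.97 ± 0.63, Traf3ip3 to -0.96 ± 0.67 and Bin1, which bends membranes, to -0.93 ± 0.65. The 8 genes that rose did so by small amounts, from 0.11 for Dpcd to 0.31 for Tspyl1, and the others were Pwp1, Fam83h, Vps33b, Trip6, Tmem129 and Dusp8. The mean of Tspyl1 rested on rat 4137, at 0.85, and without this rat it was 0.14 (adjusted p = 0.21). All 33 also lost it without rat 4135, 4136 or 4138 (up to 0.531, 0.298 and 0.484). Each of 24 rats of other groups ended between 2 and 12 calls (adjusted p up to 0.0607). Of the T cell genes, 6 fell and 0 rose (9 and 0 over the list alone, median -0.28, adjusted p = 6.97e-08, or 0.051 with estimated correlation). Of 20 NK and cytotoxic genes, 3 fell and 0 rose (3 and 0 over the list alone, median -0.051, adjusted p = 0.0177, or 0.195 with estimated correlation). The granzyme Gzma fell to -0.39 ± 0.29. Among the ribosomal genes, 4 fell and 0 rose (26 and 0 over the list alone, median -0.39, adjusted p = 9.78e-18, or 0.214 with estimated correlation). Among those of oxidative phosphorylation, 2 fell and 0 rose (9 and 1 over the list alone, median -0.20, adjusted p = 1.52e-10, or 0.214 with estimated correlation). Among those of the proteasome, 1 fell and 0 rose (4 and 0 over the list alone, median -0.14, adjusted p = 1.76e-06, or 0.222 with estimated correlation). Among the erythroid genes, 1 fell and 0 rose (6 and 0 over the list alone, median -0.086, adjusted p = 0.00188, or 0.195 with estimated correlation). Among the neutrophil genes, 0 rose and 0 fell (0 and 0 over the list alone, median 0.087, adjusted p = 0.00494, or 0.214 with estimated correlation). Among the heat shock genes, 2 fell and 0 rose (4 and 0 over the list alone, median -0.043, adjusted p = 0.0217, or 0.222 with estimated correlation), and this list had adjusted p = 0.0657 without rat 4135. The dye strength means of the 150, 1500 and 2500 mg/kg rats at 12 h were 0.76, 1.18 and 1.35, beside ribosomal list medians of -0.14, -0.38 and -0.39. With the dye profile removed over named probes these medians were -0.13, -0.42 and -0.40, and the calls stood.

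Against the control at 12 h, 759 probes passed after 1500 mg/kg (261 higher and 498 lower) and 101 after 2500 mg/kg (4 higher and 97 lower). The ratios of rat 4137, in the 2500 mg/kg group, had the lowest spread over genes (SD 0.13) and a mean correlation of 0.016 over genes with the other rats of its group. Its 2 arrays correlated by 0.86 before turning, the highest of all rats, and the medians of all 22 lists lay between -0.018 and 0.018. With the dye profile allowed for, the slopes of its arrays on the mean of the other rats of its group were -0.037 and 0.044, against 0.64 to 1.14 in those rats. With a response like theirs, 2 arrays of the same dye orientation would have full slopes of opposite sign, which was not seen. Whether the rat hardly responded or a control sample took the place of the treated one is not known. Kept as labelled, the rat pulls the means and list medians of 2500 mg/kg at 12 h towards 0. Without it the second count was 861. Without rats 4135, 4136 and 4138 it was 0, 1 and 2. Each of 19 rats of other groups moved it, to between 53 and 361. The first count was 239 without rat 4132 and 1753 without rat 3631. Allowing for the spread of the control, taken as a pool of 4 animals, gave 44 and 0 for these doses. With the rats of 12 h alone the counts were 27 and 0, and with scaled arrays that of 2500 mg/kg was 0. Between doses at 12 h, 0, 0 and 0 probes passed with limma for 1500 against 150, 2500 against 150 and 2500 against 1500 mg/kg, with 1456, 1156 and 1312 at an unadjusted p under 0.05. Without rats 4134 and 4133 the first was 66 and 31 and the last 98 and 44, while other single rats gave at most 8. For 1500 against 150 mg/kg 8 of the 22 lists were called, those of glucocorticoid response, interferon, neutrophil and monocyte genes upwards and those of platelet, T cell, ribosomal protein and oxidative phosphorylation genes downwards. The monocyte median was 0 beside its upward test. The lowest p was that of the 23 glucocorticoid response genes, of which 0 passed over all genes and 7 were higher over the list alone (median 0.11, camera adjusted p = 4.98e-07). For 2500 against 150 mg/kg the glucocorticoid and neutrophil lists were called upwards and the T cell, ribosomal and oxidative phosphorylation lists downwards. For 2500 against 1500 mg/kg the platelet list was called upwards (adjusted p = 0.000254) and the interferon list downwards (0.0173). With an estimated correlation 0 lists passed in these 3 comparisons, with a lowest adjusted p of 0.168 in the first, 0.367 in the second and 0.531 in the last. With scaled arrays the ribosomal, oxidative phosphorylation, neutrophil, monocyte and interferon calls ended (adjusted p from 0.0514 to 0.531), apart from the interferon call of the first comparison. The ribosomal, oxidative phosphorylation and monocyte calls, the T cell call of the first comparison and the interferon call of the last also ended without some single rat (up to 0.759).

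After 150 mg/kg, 193 genes passed at 6 h and 182 at 12 h, and the 3 highest and 3 lowest are given. At 6 h, Nptx1, a pentraxin, rose by 1.60 ± 0.57 (SD, n = 4 rats; limma adjusted p = 0.0158), the ubiquitin ligase Hectd2 by 1.25 ± 0.44 and Ndufa4, a subunit of the respiratory chain, by 1.21 ± 0.48, with 3, 4 and 4 of their 8 array values at exactly 0. Irf2bpl fell to -1.59 ± 0.32, the transcription factor Sox15 to -1.32 ± 0.29 and Akirin2, which carries proteasomes into the nucleus, to -1.03 ± 0.030. At 12 h, with 3 rats, Trim29 rose by 1.13 ± 1.71, Coq4, which acts in coenzyme Q synthesis, by 0.79 ± 0.45 and Cttnbp2nl by 0.79 ± 0.89. Akirin2 fell to -0.94 ± 0.015, Sox15 to -0.92 ± 0.047 and Irf7, a regulator of interferon genes, to -0.86 ± 0.31. Of 50 ribosomal protein genes at 12 h, 0 fell and 0 rose (4 and 0 over the list alone, median -0.14, adjusted p = 0.000274, or 0.747 with estimated correlation). Of 32 interferon response genes at 12 h, 2 fell and 0 rose (2 and 0 over the list alone, median -0.074, adjusted p = 0.00847, or 0.747 with estimated correlation). In the proteasome list at 12 h, 0 fell and 0 rose (0 and 0 over the list alone, median -0.085, adjusted p = 0.00847, or 0.747 with estimated correlation). Without rat 4130 all 3 lists had adjusted p = 0.0832. At 6 h and at 24 h 0 of the 22 lists were called at this dose. In probes, 419 passed at 6 h (261 higher and 158 lower) and 294 at 12 h (176 higher and 118 lower). With the rats of a time alone the counts were 1919 and 0, and with scaled arrays 1100 and 1807. Allowing for the spread of the control as a pool of 4 animals gave 9 and 0. Without single rats the first ran from 133 to 1153 and the second from 5 to 1343. Of the 6 genes called at 6 h, 3, 3, 4 and 4 lost their call without rats 3587, 3588, 3589 and 3590 (adjusted p up to 0.263, 0.130, 0.216 and 0.117). Each of 21 rats of other groups ended 1 call (up to 0.0614). Of the 6 at 12 h, 4, 5 and 6 lost it without rats 4127, 4128 and 4130 (up to 0.124, 0.482 and 0.738). Each of 23 rats of other groups ended between 1 and 3 calls (up to 0.0592). With widened standard errors all 6 calls ended at each time, and with only the rats of 12 h all 6 of that time (up to 0.247).

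The change of the dose difference over time was tested directly, as the difference between 2500 and 150 mg/kg at a later time minus that at an earlier one. From 6 to 24 h it grew by log2 3.83 ± 0.67 for S100a8 (SE; limma adjusted p = 0.00137), 3.14 ± 0.70 for Serpinb1a and 3.11 ± 0.76 for S100a9. It moved by -2.21 ± 0.33 for Cmas, -2.07 ± 0.38 for Gpx1 and -1.98 ± 0.28 for Kpna1. For the neutrophil genes, 4 were higher and 0 were lower (7 and 0 over the list alone, median 0.28, adjusted p = 1.09e-06, or 0.0292 with estimated correlation). For the erythroid genes, 7 were lower and 0 were higher (10 and 0 over the list alone, median -0.23, adjusted p = 1.41e-06, or 0.0292 with estimated correlation). From 12 to 24 h it moved by 3.27 ± 0.73 for Serpinb1a, 1.36 ± 0.29 for Alox5 and 1.31 ± 0.28 for the carboxylesterase Ces1c. It moved by -2.08 ± 0.40 for Myl9, -1.96 ± 0.40 for Pla2g2a and -1.86 ± 0.33 for Pla1a. In Serpinb1a the 150 mg/kg rats at 24 h had a mean of -1.06, which adds to both changes. From 6 to 24 h 273 probes passed (52 higher and 221 lower), from 12 to 24 h 38 (4 higher and 34 lower), and from 6 to 12 h 0 with limma, with 1375 at an unadjusted p under 0.05. Without rats 3587 and 3595 the first count was 180 and 153. The second lay between 1 and 59 without 23 single rats and was 1 without rat 3617, 3620, 4127 or 4136. The last was 1 without rat 3595. With scaled arrays the second count was 2, and with only the rats of both times 1, and all 6 genes of this change lost their call under each (adjusted p from 0.0535 to 0.147 and from 0.191 to 0.230). Of the 6 genes of the change from 6 to 24 h, 3 lost it with scaled arrays (up to 0.172) and 1 with only the rats of both times (0.0525). The call of S100a9 ended without rats 3590, 3597, 3598, 3619, 3620, 3628 or 3630 (adjusted p from 0.0529 to 0.0586). All 6 genes of the change from 12 to 24 h lost their call without rat 4127 or rat 4128 (adjusted p up to 0.0932 and 0.181). Between 1 and 5 of them lost it without any of 20 other rats, with the highest adjusted p, 0.137, without rat 4137.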

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

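The tests of the neutrophil and T cell pattern, all counts of other splits of the rats, the split by dose, the comparison without rat 4137, and the removal of the dye profile with slopes over named probes were chosen only after the results were seen.

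The first pattern weighed is the rise of neutrophil genes with the fall of T cell genes at 24 h after 1500 and 2500 mg/kg. Unequal dye strength of the arrays of a rat is argued against, since the neutrophil minus T cell list median was 0.66 ± 0.14 (SD over 8 rats) before and 0.64 ± 0.17 after the dye profile was removed. A lower share of lymphocytes alone is argued against as well, since it would raise neutrophil, erythroid and platelet genes alike. In 8 of 8 rats the neutrophil median lay above both others. The group medians of these lists were already known, so this count restates them by rat and is no separate support. More neutrophils in the blood stays open and cannot be told apart from a change within the cells: a rise of these cells may raise every list member, at most 1 member fell at either dose, and cells were not counted in the sources used here. A response to the drug also stays open, as an untested hypothesis beyond the tests of dose.

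The second pattern is the 419 and 294 probes called against the control at 150 mg/kg at 6 and 12 h, where the control's own deviation would shift all doses of a time alike. The 200 genes most extreme in 2 of the 150 mg/kg rats were compared with the rats held out, a single rat at 12 h. At 12 h the mean at 1500 mg/kg was 1.08 times that of the held-out rats and at 2500 mg/kg 0.888 times. For these genes this argues against growth to over 1.5 times, while a control deviation and a drug effect full at 150 mg/kg stay open. The called probes were not tested. Rat 4137 pulls the second ratio down, and without it the ratio was 1.18 (1.08 to 1.25 with the rats picked), so that a smaller growth stays open too. At 6 h the ratios were 1.01 and 0.738, which again argues against such growth. The control's deviation cannot be told apart there because the ratios ranged from 0.659 to 1.40 and from 0.297 to 1.20 with the rats picked.

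The third pattern is a split of the 8 rats of 1500 and 2500 mg/kg at 24 h that calls 5340 probes, where the split by dose calls 0. That 0 was known before, so it weighs nothing about the doses. Unequal dye strength as the whole cause is argued against by the 4078 probes left after the dye profile was removed with slopes over all probes and the 3010 left with slopes over named probes. Part of it may still be dye strength, since the difference between the sides of this split correlated with the dye profile by 0.679 over named probes, and the slopes of the paired arrays differed by -0.0045 to 0.96 on one side (rats 3625, 3626, 3628 and 3629) and by -1.66 to -0.53 on the other. These sides were chosen by the size of their difference.

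Counts of probes in other splits of the same rats were compared with the real ones. Chance can be excluded for 2500 against 150 mg/kg at 6 h (18 probes, highest other 1; 1 of 35 splits as large), for 1500 against 150 mg/kg at 24 h (281, highest other 3; 1 of 35) and for 2500 against 150 mg/kg at 24 h (1152, highest other 639; 1 of 35). For the changes over time the draws argue against chance from 6 to 24 h (273, highest other 97, 1 of 100). From 12 to 24 h the margin is small (38, highest other 19, 1 of 100), with 1 probe left without some single rats. For 1500 against 150 mg/kg at 6 h the share of splits alone argues against chance (3, highest other 1, 1 of 35). The margin is small there, since the real count was 1 without any one of 7 rats. Where the real count was 0, every split gives as many by construction, so the splits decide nothing. This held for 35 of 35 splits of 2500 against 1500 mg/kg at 6, 12 and 24 h (highest other 0, 3 and 5340). It also held at 12 h for 2500 against 150 mg/kg (highest other 1, 35 of 35). So it did for the change from 6 to 12 h (highest other 1, 100 of 100). For 1500 against 150 mg/kg at 12 h the 10 splits are too few for a share under 0.05 (0, highest other 0; 10 of 10). The split with 5340 probes crosses the doses, and part of it may be dye strength.

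Single rats lay far from the others of their group in 9 of 163 groups of values. Those of 3 rats could not be marked, and chance would mark about 1 in 20 others. At 6 h after 2500 mg/kg, rat 3595 had a log2 ratio of 2.60 for Gipc2 (others 0.17 to 0.35) and 2.71 for Myo5a (others 0.15 to 0.31). At 12 h after 2500 mg/kg, rat 4137 had 0.85 for Tspyl1 (others 0.12 to 0.16). At 24 h after 1500 mg/kg, rat 3624 had -1.48 for Ranbp10 (others -1.95 to -1.89). After 2500 mg/kg, rat 3631 had 0.99 for S100a9 (others 3.66 to 3.98) and rat 3628 2.31 for Rbp4 (others 1.20 to 1.28). Rat 3631 had an oxidative phosphorylation list median of -0.51 at 24 h after 2500 mg/kg (others -0.14 to -0.066), rat 3618 a platelet list median of -0.14 at 24 h after 150 mg/kg (others 0.058 to 0.092), and rat 3588 a T cell list median of 0.050 at 6 h after 150 mg/kg (others -0.11 to -0.089).

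The difference between 2500 and 150 mg/kg changed over time by the tests of the change itself, with 273 probes from 6 to 24 h and 38 from 12 to 24 h. The second count was 2 with scaled arrays and 1 with only the rats of both times, and all 6 of its named genes lost their call under each. From 6 to 24 h it moved by 3.83 for S100a8, 3.14 for Serpinb1a, 3.11 for S100a9, -2.21 for Cmas, -2.07 for Gpx1 and -1.98 for Kpna1, and from 12 to 24 h by 3.27 for Serpinb1a, 1.36 for Alox5, 1.31 for Ces1c, -2.08 for Myl9, -1.96 for Pla2g2a and -1.86 for Pla1a. From 6 to 12 h the erythroid list moved by a median of -0.11. From 6 to 24 h the list medians moved by -0.23 (erythroid), 0.28 (neutrophil), -0.019 (platelet), 0.073 (inflammatory signalling), -0.14 (ER stress), -0.25 (cytosolic ribosomal proteins), -0.15 (proteasome) and 0.093 (liver-enriched). From 12 to 24 h they moved by -0.040 (erythroid), 0.25 (neutrophil), -0.28 (platelet), -0.14 (ER stress), -0.31 (cytosolic ribosomal proteins), -0.15 (proteasome) and 0.11 (liver-enriched). Several of these list changes rested on single rats. Without rat 3631 the platelet change was 0.068 from 6 to 24 h (adjusted p = 0.366) and -0.030 from 12 to 24 h (0.415). Without rat 3596 the calls from 6 to 24 h of the ribosomal, ER stress, proteasome, inflammatory, liver and platelet lists ended (0.668, 0.132, 0.132, 0.109, 0.0584 and 0.0525). That of platelets also ended without rat 3588 (0.0575) and the ribosomal one without rat 3631 (0.0776). From 6 to 24 h the inflammatory call also ended without rats 3618, 3628 or 3630 (up to 0.0951), and that of ER stress without rats 3595, 3629 or 3630 (up to 0.077). From 12 to 24 h the erythroid call ended without rats 3628 or 4137 (0.136 and 0.0758) and that of the proteasome without rats 3631 or 4137 (0.0719 and 0.0953). That of ER stress ended without rats 3628, 3630, 4127 or 4137 (up to 0.0818). With scaled arrays the calls from 6 to 24 h of the ribosomal, platelet, proteasome and ER stress lists ended (0.644, 0.169, 0.1 and 0.0538). Without rats 3631 and 4137 together the call from 12 to 24 h of the ribosomal list ended too (0.444). With an estimated correlation, the calls of the neutrophil and erythroid lists from 6 to 24 h held, and the other 14 did not.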

How the results depend on the processing

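Counts of probes moved with the settings below, by more than 1.5 times or to or from 0. The opposite sign turns every result by construction. Under the other settings the direction of no test turned, but some list medians did. Without rat 3631 the platelet list median at 24 h turned from -0.10 to 0.029 after 2500 mg/kg against the control. It turned from -0.27 to 0.043 against 150 mg/kg, from -0.10 to 0.030 against 1500 mg/kg, and from -0.019 to 0.068 for the change from 6 to 24 h, and did so too without rats 3631 and 4137 together. The glucocorticoid response list median at 24 h after 1500 mg/kg turned from 0.015 to -0.0018 without rat 3626. The B cell list medians of 1500 and of 2500 against 150 mg/kg at 6 h, -0.0086 and 0.0010, lay so close to 0 that some settings turned them. Setting array medians to 0, robust moderation and the opposite sign moved no total count. Where nothing else is said, the cause of a move was not tested.

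Scaling the arrays to the same spread gave 1100, 6246 and 4470 probes against the control at 6 h after 150, 1500 and 2500 mg/kg. At 6 h it gave 347 for 1500 against 150 and 120 for 2500 against 150 mg/kg. At 12 h it gave 1807 against the control after 150 and 0 after 2500 mg/kg. At 24 h it gave 161 for 1500 against 150 mg/kg. For the changes over time it gave 21 from 6 to 12 h and 2 from 12 to 24 h.

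Keeping the arrays apart, with a dye term, gave 789 probes against the control at 6 h after 150 mg/kg, and 275, 86 and 19 for 1500 against 150, 2500 against 150 and 2500 against 1500 mg/kg. At 12 h it gave 827, 1443 and 981 against the control by rising dose, and 100, 1 and 36 for the same pairs of doses. At 24 h it gave 1831 against the control after 1500 mg/kg, and 644, 2242 and 36 for the pairs. The changes over time had 32 (6 to 12 h), 586 (6 to 24 h) and 221 (12 to 24 h).

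With only the rats of the times compared, the counts against the control were 1919, 4323 and 3253 at 6 h by rising dose, 0, 27 and 0 at 12 h, and 358 and 993 at 24 h after 1500 and 2500 mg/kg. Between doses they were 41 and 44 at 6 h and 46 and 112 at 24 h, for 1500 and 2500 against 150 mg/kg. The changes had 1 from 6 to 12 h and 1 from 12 to 24 h.

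Widening the standard errors for the control animals lowers counts by construction. It gave 9, 408 and 186 at 6 h by rising dose, 0, 44 and 0 at 12 h, and 405 and 1611 at 24 h after 1500 and 2500 mg/kg. It applies to comparisons with the control alone, where 139 of 261 called results for named genes kept their call. With the 12 changes over time, to which it was not applied, 151 of 273 stood. Counting genes in place of probes, of which there are fewer, gave 193, 1228 and 745 at 6 h by rising dose, 182 and 467 at 12 h after 150 and 1500 mg/kg, 2559 at 24 h after 2500 mg/kg, and 738 for 2500 against 150 mg/kg at 24 h. With an estimated correlation, 18 of the 131 called gene lists passed.

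Leaving out the 20% of probes with the poorest agreement of dyes gave 8 for 1500 against 150 mg/kg at 6 h and 172 against the control at 12 h after 2500 mg/kg. Removing the dye profile, an alternative chosen after seeing the data, gave 5 for 1500 against 150 mg/kg at 6 h with slopes over all probes. With slopes over named probes it gave 6 there, 182 against the control at 12 h after 2500 mg/kg, 1 for 1500 against 150 and 1 for 2500 against 1500 mg/kg at 12 h, and 23 for the change from 12 to 24 h.

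Leaving out rats 3631 and 4137 together, also chosen after seeing the data, gave 1173, 3468 and 2355 against the control at 6 h by rising dose, and 17 for 1500 against 150 mg/kg. At 12 h it gave 1366, 1795 and 1674 against the control, 4 for 1500 against 150 and 1 for 2500 against 1500 mg/kg. At 24 h it gave 1836 against the control after 1500 mg/kg and 436 for 1500 against 150 mg/kg, and 12 for the change from 12 to 24 h.

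Leaving out each rat in turn gave these lowest and highest counts. Against the control they were 133 and 1153, 1094 and 3470, and 575 and 2366 at 6 h by rising dose. At 12 h they were 5 and 1343, 239 and 1753, and 0 and 861. At 24 h they were 0 and 1 after 150 mg/kg and 582 and 1809 after 1500 mg/kg. For 1500 against 150 mg/kg they were 1 and 14 at 6 h, 0 and 66 at 12 h, and 166 and 402 at 24 h. For 2500 against 150 mg/kg they were 3 and 25, 0 and 3, and 633 and 1752. For 2500 against 1500 mg/kg they were 0 and 2, 0 and 98, and 0 and 12. The changes over time had 0 and 1 (6 to 12 h), 153 and 326 (6 to 24 h) and 1 and 59 (12 to 24 h).

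Among the 273 called results for a named gene in a comparison, 60 lost their call with scaled arrays and 91 with only the rats of the times compared. Of the 131 called gene lists 19 lost their call with scaled arrays, which was added after seeing the data. With the dye profile removed 129 kept it (slopes over all probes) or 126 (named probes).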

Other observations

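Genes that answer oxidative stress moved both ways at 24 h. Those named here were chosen after their values were seen, and no further test was made of them. Cat, which codes for catalase, fell to -1.29 ± 0.14 (SE, n = 4 rats; limma adjusted p = 2.19e-07) after 1500 mg/kg and to -1.50 ± 0.14 after 2500 mg/kg. Blvrb, the biliverdin reductase of red cells, fell to -0.87 ± 0.12 (1.07e-05) and -1.07 ± 0.12 (3.14e-07). Gclm, which helps to make glutathione, fell to -0.73 ± 0.086 (8.34e-07) and -0.57 ± 0.086 (2.68e-05). Nqo1, a quinone reductase, rose after 2500 mg/kg by 0.78 ± 0.17 (0.00159). Hmox1, which breaks down haem, had 0.16 ± 0.036 (0.00413) and 0.11 ± 0.036 (0.02). Gadd45a, a growth arrest gene, rose by 1.05 ± 0.26 (0.00896) and 1.20 ± 0.26 (0.00136) at 24 h and by 1.07 ± 0.30 (0.0361) at 12 h after 1500 mg/kg. Cdkn1a, a further p53 target, had 0.023 ± 0.041 (0.816) and -0.058 ± 0.041 (0.304) at 24 h. Fkbp5, a glucocorticoid-induced chaperone, rose at 6 h by 0.33 ± 0.079 (0.0052) after 1500 mg/kg and by 0.59 ± 0.079 (2.3e-05) after 2500 mg/kg. It had 0.12 ± 0.079 (0.252) at 24 h after the latter dose.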
